A study of Mus musculus with 15 samples.

How the data were processed

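Single-cell RNA sequencing of CD8+ T cells from mice bearing B16F10, a melanoma cell line injected intravenously, was analysed here. Of the 15 samples, 10 are gene expression libraries from 5 groups. The 5 T cell receptor libraries were not used here. Per the labels' protocols, mice lacking the class Ia molecules H2-Kb and H2-Db (called null mice below) received cells with MHC class Ia (Ia+) or without it (Ia-) into the peritoneum every 3 days from day 0, and cells were isolated after 9 days. The injected cells are named MCs in the earlier and MSCs in the later deposit set, and the abbreviations are not explained in the sources used here. C57BL/6 mice received none of these cells, so genotype and injection differ together. The groups were C57BL/6 spleen, C57BL/6 tumor, null Ia+ spleen, null Ia+ tumor and null Ia- spleen. No tumor library of null Ia- mice was used here. Tumor cells came from lung digested with collagenase and enriched on a Percoll gradient, and CD8+ T cells were isolated from tumor and spleen with magnetic beads, per the labels' protocols.

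Each group had 2 libraries, 1 in each of the 2 deposit sets. Replicate 1 is the library of the earlier set and replicate 2 that of the later set. For the earlier set the labels name a standard 10x protocol, polyA RNA, the genome mm10, CASAVA 1.8, Cell Ranger and Seurat, and the end of the transcript that was read is not given in the sources used here. For the later set the labels name a 10x 5' kit, total RNA, GRCm38, CASAVA 1.8 and Seurat 4.0.3. Cell Ranger 6.1.1 made the later matrices per the file headers, and the submitters' processing notes list 6.1.10 as well. The replicates are not stated to be separate animals, so every p-value measures the spread between these libraries.

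The deposited values are raw UMI counts per gene and cell barcode, a count of molecules made with Cell Ranger per the labels. The other deposited files hold gene IDs with symbols and cell barcodes, and no measurement. In the earlier set 4 of the 5 libraries hold a round number of barcodes, and the lowest UMI count per barcode was 1556 there and 500 in the later set. Genes were joined by Ensembl ID. The annotations hold 27998 and 31253 genes, of which 27046 were in both, 1471 of these with a changed symbol. These shared genes held 98.9% to 99.7% of the UMIs of each library. Any pair of libraries shared 34 to 100 barcodes, so none was deposited under 2 names.

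Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 70411 of 71249 barcodes. Scrublet (through scanpy 1.11.5, expected rate 6%) marked 9 cells and at most 0.0432% of a library. That is under 0.5%, so the caller is taken not to have worked, and removal of the highest 6% of its scores was added as an alternative after the data were seen. Cells were scaled to 10000 per cell and clustered within each deposit set on 2000 variable genes (T cell receptor, immunoglobulin, ribosomal and mitochondrial genes left out), 30 principal components and 15 neighbours with Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, anndata 0.12.19, seed 1). This gave 38 clusters in the earlier and 32 in the later set, of which 11 and 16 were named CD8 T-like. Names came from markers fixed before the data were examined. The thresholds of the naming were set after seeing the data. A CD8 T-like cluster had a UMI of Cd3e, and of Cd8a or Cd8b1, in at least 50% of its cells, more Cd8 than Cd4 UMIs, and a mean log2 fold of at most 1 for the markers of any other type. A cluster of another type had a mean log2 fold over 1.5 for its markers, with at least 3 of them detected in 10% of cells. Naive-like and antigen-experienced-like CD8 clusters had a mean log2 fold over 0.5 for the markers of that state. Clusters that these thresholds kept unnamed are given per library with the cell types. Leading genes of some CD8 T-like clusters include H2-D1 and H2-K1, the targeted genes.

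In 3 CD8 T-like clusters the 10 leading genes held 1 marker of another type and none of CD8 T cells. They are cluster 3 of the earlier set (Izumo1r, while Cd8b1 had a UMI in 90.4% and Cd4 in 0.126% of its cells), cluster 3 of the later set (Klre1, Cd8b1 76.3%, Cd4 0.0724%) and cluster 13 of the later set (Izumo1r, Cd8b1 75.2%, Cd4 8.53%). In the earlier set they held 0.516% of the CD8 T-like cells of C57BL/6 spleen, 1.27% of C57BL/6 tumor, 17.6% of null Ia+ spleen, 0% of null Ia+ tumor and 43.5% of null Ia- spleen. In the later set these shares were 4.62%, 0.793%, 10.8%, 0.476% and 35.6%. The design fixed before the data were examined keeps these clusters, so each count of changed genes is given with and without them. The fit without them was chosen after seeing the data.

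UMIs were summed per library over CD8 T-like cells and tested with edgeR 4.0.16 (quasi-likelihood test with robust estimates, TMM factors of 0.813 to 1.20, filterByExpr by group, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The fit held all 10 libraries with a term for the deposit set and had 4 residual degrees of freedom. It tested 12934 genes with a common biological coefficient of variation of 0.232. Same-set libraries deviate together: across genes, the difference between the sets correlated between groups with r of 0.575 to 0.839 over the 10 pairs of groups (genes are not independent replicates). The pairing comes from the deposit sets, which differ in protocol and processing per the labels, and why same-set libraries deviate together was not tested. Adjusted p-values named in the text are from edgeR unless another tool is named. Values per library are CPM (UMI counts over the library total times its TMM factor, scaled to a common total) in CD8 T-like cells, and differences within a set are log2 of CPM with 1 added. Errors are standard errors of the fitted log2 fold change, or SD over n = 2 libraries where marked.

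The 33 gene lists were tested with limma 3.58.1: fry on voom values (prior count 2 for log2 CPM) asks whether the genes of a list move on balance one way and does not compare them with other genes. Camera with an estimated correlation, which compares a list with the other genes, was the alternative. Beside each test stands the number of members past the edgeR threshold over all genes and adjusted over the list alone. The lists are cytotoxic effector, effector differentiation, inhibitory receptors and exhaustion, naive and quiescence, memory-like, tissue residency, proliferation, interferon response, cytokines and chemokines, chemokine receptors and integrins, NK receptors, immediate early, heat shock and dissociation, glycolysis, oxidative phosphorylation, fatty acid and sterol, MHC Ia antigen presentation, MHC Ib, T cell receptor signalling, apoptosis and survival, and markers of 13 other cell types (B, CD4 T, gamma-delta or NKT, NK, macrophage or monocyte, dendritic, neutrophil, mast or basophil, erythroid or platelet, melanoma, lung epithelium, endothelium and stroma). The files gave no match for 14 members, among them every constant gene of the gamma-delta list. Lists overlap, and several NK and macrophage markers are also expressed by activated CD8 T cells.

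Genes named in the text follow a rule written before the data were examined. H2-K1, H2-D1, B2m, Cd8a, Cd8b1 and Cd3e are always included. Of the genes past the threshold with the same sign in both sets and a mean of at least 20 CPM in the higher group, the 8 largest increases and 8 largest decreases are eligible, leaving out receptor, immunoglobulin, ribosomal, mitochondrial and predicted genes and markers of other cell types. From each list come up to 3 members past the threshold, or else the member with the largest change as a value. For the tumor against spleen comparisons, the largest changes among genes not higher in the cells outside the CD8 T-like clusters (CPM there without TMM factors) were added after the values were seen. Counts of genes with a larger share of the UMIs outside those clusters use no TMM factor and have no baseline over all tested genes. Some genes that the rule names are not reported here. Gene positions are from GENCODE vM21 on GRCm38.

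The test was tested on simulated data for C57BL/6 tumor against spleen (12667 genes, 200 of them changed). It recovered 66% of 100 genes changed 4-fold and 20% of 100 genes changed 2-fold, with 12 false calls among 98. It made 2 calls for null Ia+ against null Ia- spleen, which was simulated unchanged. For shares of cells with a UMI each cell was thinned to 1000 UMIs and shallower cells were left out. Intervals are exact binomial at 95%, the upper limit of a count of 0 is that of 3 counts, and all of these cover counting error only. Groups of 2 libraries allow no test for outlying libraries and no count of other splits.

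Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, no low-count filter, no replicate block (no deposit-set term), all cells, cells gated by UMIs, antigen-experienced-like or naive-like clusters only, a limit of 5% mitochondrial UMIs, doublets kept, libraries thinned to the smallest total, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the tables and figures.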

Results

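Gene expression of bead-isolated CD8+ T cells was measured by droplet single-cell RNA sequencing in 10 libraries, 2 for each of 5 groups of mice bearing B16F10 melanoma cells. The groups were C57BL/6 spleen, C57BL/6 tumor, null Ia+ spleen, null Ia+ tumor and null Ia- spleen, where null mice lack H2-Kb and H2-Db and Ia+ or Ia- names the injected cells. In that order the earlier set held 30988966, 87403571, 66917096, 37993713 and 23211254 UMIs, and the later set 40628046, 49422873, 36629281, 55160147 and 40864592. Between 1968 and 7382 cells per library were CD8 T-like, and these carried 8694645 to 51945995 UMIs with a median of 2662 to 7056 UMIs per cell.

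The targeted genes separated the null from the C57BL/6 libraries in both sets. H2-D1 (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499, GRCm38) stood at 3145 and 1688 CPM in C57BL/6 spleen and at 3677 and 2267 CPM in C57BL/6 tumor. It stood at 1.59 and 0.802 CPM in null Ia+ spleen, 1.46 and 0.753 CPM in null Ia+ tumor, and 0.808 and 0.782 CPM in null Ia- spleen. H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347) averaged 2282 ± 366 CPM (SD, n = 2) in C57BL/6 spleen and 2218 ± 262 in C57BL/6 tumor. It averaged 266 ± 27.8 in null Ia+ spleen, 401 ± 124 in null Ia+ tumor and 237 ± 169 in null Ia- spleen. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083) averaged 3536 ± 2003, 3849 ± 2468, 3686 ± 1890, 3773 ± 1817 and 3457 ± 1488 CPM in the 5 groups in the order named above, and differed by set more than by group. These values check the library labels. Counted tags may come from parts of a gene outside its deletion, and paralogs of H2-K1 share sequence with it, so the H2-K1 level left in null mice is not a measure of intact transcript.

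**Figure D1:**
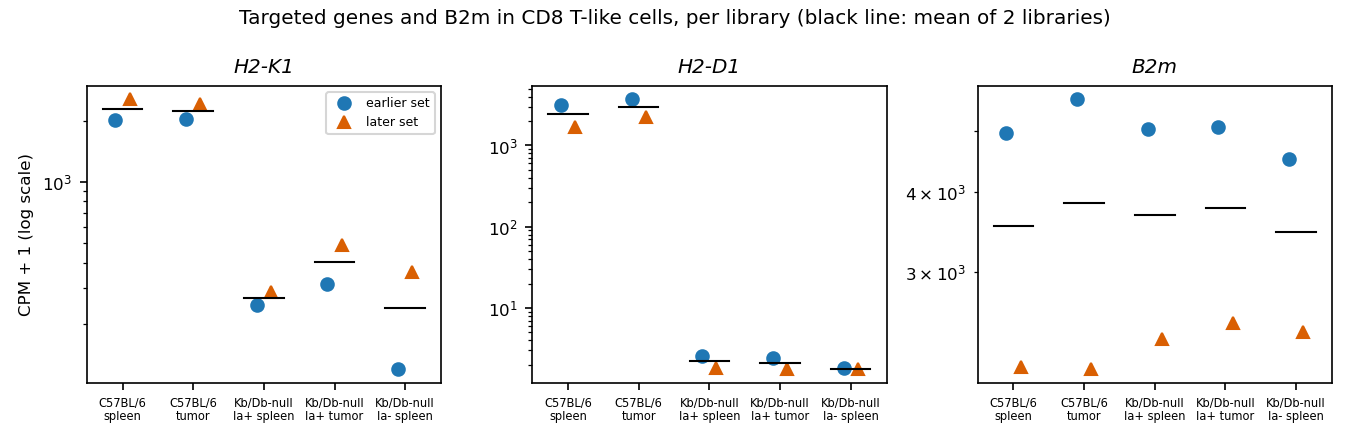
CPM plus 1 (log scale) of H2-K1, H2-D1 and B2m in CD8 T-like cells of each library, with a black line at the mean of the 2 libraries of each group. H2-D1 lies at or under 1.59 CPM in all 6 null libraries and at or above 1688 CPM in the 4 C57BL/6 libraries.

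CD8 T-like cells made up 96.0% (exact binomial 95% interval 95.6% to 96.5%) and 94.1% (93.5% to 94.6%) of the filtered cells of the C57BL/6 spleen libraries, earlier set first. They made up 40.3% (38.9% to 41.7%) and 87.6% (86.8% to 88.3%) in C57BL/6 tumor, and 55.5% (54.3% to 56.7%) and 76.5% (75.5% to 77.5%) in null Ia+ spleen. In null Ia+ tumor they were 65.8% (64.7% to 66.8%) and 93.0% (92.3% to 93.6%), and in null Ia- spleen 62.9% (61.7% to 64.1%) and 79.8% (79.0% to 80.6%). In the earlier C57BL/6 tumor library, melanoma-like cells were 29.0% (27.7% to 30.3%), epithelial-like cells 8.51% (7.75% to 9.33%) and stromal-like cells 4.71% (4.13% to 5.34%). The earlier null Ia+ tumor library held 9.06% (8.44% to 9.71%) NK-like and 7.46% (6.89% to 8.05%) stromal-like cells. The earlier null Ia+ spleen library held 9.64% (8.96% to 10.4%) erythroid- or platelet-like, 6.73% (6.15% to 7.35%) NK-like and 5.0% (4.50% to 5.54%) mast- or basophil-like cells. In the later set, B-like cells were 5.45% (4.92% to 6.01%) and macrophage-like cells 5.37% (4.85% to 5.94%) of null Ia+ spleen, and B-like cells were 7.53% (6.99% to 8.10%) of null Ia- spleen. Cd3e-positive clusters low in Cd8a and Cd8b1 were left unnamed and were 2.49% to 18.0% of the earlier libraries, with the highest share in null Ia- spleen. Outside C57BL/6 spleen the libraries of a group lay far apart, as C57BL/6 tumor shows, so no share of cell types was compared between groups.

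**Figure D2:**
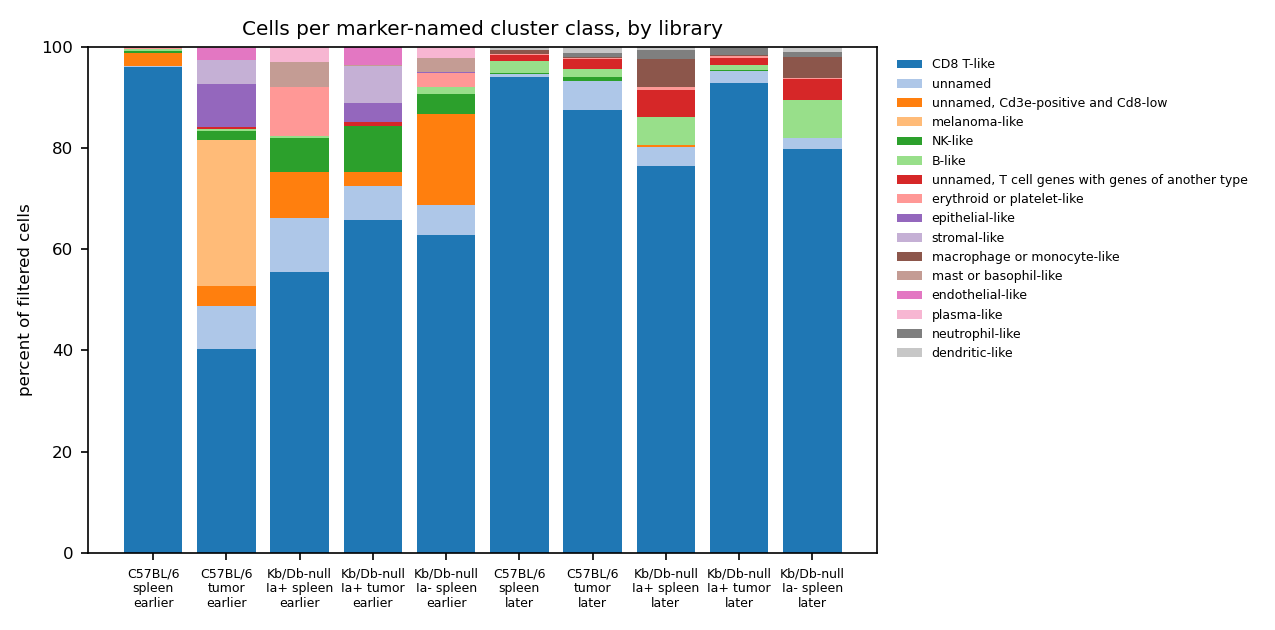
Percent of filtered cells in each cell class (stacked bars) for each of the 10 libraries. CD8 T-like cells range from 40.3% in the earlier C57BL/6 tumor library to 96.0% in the earlier C57BL/6 spleen library.

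The largest CD8 T-like cluster differed between most groups. In the earlier set, the largest cluster of C57BL/6 spleen (cluster 0, 61.9% of its CD8 T-like cells) was led by Ccr9, H2-D1 and Dapl1, and that of C57BL/6 tumor (cluster 5, 73.2%) by Ccr7, Dusp10 and Fam241a. The largest cluster of null Ia+ spleen (cluster 4, 43.1%) was led by S1pr5, Zeb2 and Cx3cr1. That of null Ia+ tumor (cluster 1, 83.8%) was led by Esm1, Gzmb and Gm4208, and that of null Ia- spleen (cluster 2, 49.1%) by Gzmm, Klra6 and Samd3. In the later set, the largest cluster of C57BL/6 spleen (cluster 0, 77.5%) was led by Ccr9, Dapl1 and Igfbp4, and that of C57BL/6 tumor (cluster 2, 57%) by Dusp10, Ccr7 and Tubb2a. Both null spleen groups had their largest share in cluster 1 of that set (36.5% with Ia+ and 40.0% with Ia- cells), led by Gzmm, Aqp9 and Dlg5. Null Ia+ tumor had its largest share in cluster 4 (42.7%), led by Isg20, Ifit1 and Ifit3. Antigen-experienced-like clusters held 108 and 371 cells in C57BL/6 spleen and 100 and 152 in null Ia- spleen, and naive-like clusters held 264 and 59 in null Ia+ tumor, so values within these states rest on few cells there. Clusters were built on these same genes, so cluster sizes were not tested between groups.

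The comparison of tumor with spleen in C57BL/6 mice asks how CD8 T cells in B16F10-bearing lung differ from those in spleen when class Ia is present. Collagenase and Percoll are described for tumor alone, so tissue and processing differ together. In tumor, the granzyme gene Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260) averaged 341 ± 127 CPM (SD, n = 2) against 16.7 ± 12.2 in spleen, and Bhlhe40, a transcription factor gene of activated T cells, averaged 103 against 3.34 CPM. Gzmb rose by 4.42 ± 0.63 on the log2 scale (edgeR adjusted p = 0.0166, 5.57 in the earlier and 3.26 in the later set) and Bhlhe40 by 5.07 ± 0.70 (adjusted p = 0.0166, 5.07 and 4.36). The death ligand gene Fasl (chromosome 1, 161780689 to 161788495) rose by 3.96 ± 0.38 (adjusted p = 0.00407, 3.85 and 3.48), and the inhibitory receptor gene Ctla4 rose by 3.91 ± 0.56 (adjusted p = 0.0161). Dusp5, a phosphatase gene induced by T cell activation (chromosome 19, 53529109 to 53542431), rose by 3.73 ± 0.23 (adjusted p = 0.00015, 3.87 and 3.46). The lectin gene Clec2d fell, with a log2 change of -2.01 ± 0.25 (adjusted p = 0.00853, -2.29 and -1.66), as did Als2cl with -1.62 ± 0.23 (adjusted p = 0.0126, -1.84 and -1.36). Gzma, given as a value, had a log2 change of 3.32 ± 0.77 and did not pass (adjusted p = 0.0695). The identity genes Cd8a (-0.61 ± 0.18, adjusted p = 0.0964), Cd8b1 (-0.27 ± 0.21, adjusted p = 0.489) and Cd3e (0.05 ± 0.25, adjusted p = 0.934) did not pass. Neither did H2-K1 (-0.03 ± 0.31, adjusted p = 0.967) or H2-D1 (0.32 ± 0.18, adjusted p = 0.324). In all, edgeR called 424 genes, 324 higher and 100 lower in tumor, 422 of them with the same sign in both sets. At an unadjusted p under 0.05 there were 2841 genes. The count was 2 without C57BL/6 spleen replicate 1, 237 without its replicate 2, 40 without tumor replicate 1 and 227 without tumor replicate 2. Of 65 called genes named by the rule Dusp5 alone passed in all 4 of these fits and 13 passed in none, Klrk1 and Klrg1 among them. Without the deposit-set term edgeR called 0 genes (1074 at an unadjusted p under 0.05), and DESeq2 called 1176 with it. EdgeR called 641 without the CD8 T-like clusters led by another type's marker.

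Some effector genes rose in C57BL/6 tumor cells. Of 16 cytotoxic effector genes 5 rose over all genes and 10 rose and 1 fell adjusted over the list alone (fry adjusted p = 0.0540, camera adjusted p = 0.267 with an estimated correlation), among them Gzmb, Fasl and Srgn, the last at -0.0534 in a fit of all filtered cells. Of 18 effector differentiation genes 8 rose (16 adjusted over the list alone, fry adjusted p = 0.0540), among them Ccr2 (2.57 ± 0.29, adjusted p = 0.00614), Anxa2 (2.50 ± 0.26, adjusted p = 0.00458), Lgals1 (1.90 ± 0.24, adjusted p = 0.00834) and Klrg1 (3.71 ± 0.62, adjusted p = 0.026). Proliferation genes rose for 5 of 20 members (18 adjusted over the list alone, fry adjusted p = 0.0700), with Hmgb2 at 1.93 ± 0.24 (adjusted p = 0.00829, 2.46 and 1.41). Tissue residency genes rose for 5 of 15 (7 adjusted over the list alone, fry adjusted p = 0.0540), with Rgs1 at 3.75 ± 0.37 (adjusted p = 0.00437). Inhibitory receptor and exhaustion genes rose for 3 of 17 (10 adjusted over the list alone, fry adjusted p = 0.0785). Immediate early genes rose for 4 of 19 (10 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.0785), with Nr4a1 at 2.66 ± 0.42 (adjusted p = 0.0193). NK receptor genes rose for 2 of 21 (6 adjusted over the list alone, fry adjusted p = 0.112), namely Klrc1 (2.83 ± 0.39, adjusted p = 0.0124) and Klrk1 (1.94 ± 0.35, adjusted p = 0.026). Chemokine receptor and integrin genes rose for 4 of 18 (5 adjusted over the list alone and 1 lower, fry adjusted p = 0.0736). Apoptosis and survival genes rose for 3 of 16 (10 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.0540). Of 18 naive and quiescence genes only Als2cl fell and 0 rose (1 rose and 1 fell adjusted over the list alone, fry adjusted p = 0.614). By fry 0 of 33 lists passed an adjusted p of 0.05 and 14 had an unadjusted p under 0.05. By camera 0 passed and 5 had an unadjusted p under 0.05. Leaving out single libraries gave 0 to 6 lists, and the population without clusters led by another type's marker gave 10.

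Some genes of other cell types rose beside them. Of 11 lung epithelium genes 3 rose (7 adjusted over the list alone, fry adjusted p = 0.0540), with Scgb1a1, a club cell secretion gene, at 5593 and 12.1 CPM in the 2 tumor libraries against 2.02 and 0 CPM in spleen. Of 5 melanoma genes Dct and Tyrp1 rose (3 adjusted over the list alone, fry adjusted p = 0.0700), Dct at 83.0 and 0.251 CPM and Tyrp1 at 76.3 and 0.114 CPM in the 2 tumor libraries, against means of 0.0429 and 0 CPM in spleen. Stroma genes rose for 3 of 8 (6 adjusted over the list alone, fry adjusted p = 0.0736) and endothelium genes for 1 of 9 (8 adjusted over the list alone, fry adjusted p = 0.0795). Of the 324 genes higher in tumor, 126 had a larger share of the UMIs outside the CD8 T-like clusters than inside in both sets, and 226 in at least 1 set. Bhlhe40, Anxa2, Nr4a1 and Mt1 were among the 126, as were Scgb1a1, Dct and Tyrp1.

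The same comparison in null Ia+ mice asks how CD8 T cells selected without H2-Kb and H2-Db differ between these tissues, which again differ in processing. Some naive-state genes fell in tumor. Dapl1 (ENSMUSG00000026989, chromosome 2, 59484653 to 59505020) averaged 6.33 ± 3.08 CPM (SD, n = 2) in tumor against 145 ± 118 in spleen, a log2 change of -4.29 ± 0.51 (adjusted p = 0.00682, -4.59 and -3.59 within the sets). It passed in 1 of the 4 fits that leave out 1 library of this comparison. Nsg2 (chromosome 11, 32000463 to 32059202) changed by -3.34 ± 0.21 (adjusted p = 0.000329, -3.39 and -2.98) and Igfbp4 by -3.06 ± 0.35 (adjusted p = 0.00566, -2.84 and -2.93), Igfbp4 with the opposite sign in a fit of all filtered cells (0.19). The activation genes Vps37b (2.80 ± 0.27, adjusted p = 0.00242, 3.28 and 2.25), Nr4a3 (2.72 ± 0.25, adjusted p = 0.0022, 2.58 and 2.42) and Dusp5 (2.48 ± 0.21, adjusted p = 0.00134, 2.61 and 2.30) rose. Fasl averaged 173 CPM in tumor against 43.6 in spleen and rose by 1.98 ± 0.34 (adjusted p = 0.0215). Ctla4 (2.52 ± 0.51, adjusted p = 0.0405) and Tigit (adjusted p = 0.0445) rose as well. Neither passed when any single library of this comparison was left out. In all, edgeR called 466 genes, 197 higher and 269 lower in tumor, 459 of them with the same sign in both sets. DESeq2 called 592 higher and 604 lower, and within cell states edgeR called more higher than lower genes (172 and 52 in antigen-experienced-like, 259 and 150 in naive-like clusters). The count was 24 without null Ia+ spleen replicate 1, 25 without its replicate 2, 197 without tumor replicate 1 and 996 without tumor replicate 2. Nsg2, Nr4a3, Dusp5, Vps37b, G0s2, Slpi, Rflnb and Cd22 passed in all 4 of these fits, of 58 called genes named by the rule. With no deposit-set term edgeR called 0 genes (1001 at an unadjusted p under 0.05). Removing the clusters led by another type's marker gave 528 genes.

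Among the gene groups of null Ia+ mice, the fatty acid and sterol list passed: 1 of 15 members rose, Insig1 (1.69 ± 0.28, adjusted p = 0.0178, 1.87 and 1.32). In that list 6 rose and 1 fell adjusted over the list alone (fry adjusted p = 0.00836, camera adjusted p = 0.395 with an estimated correlation). Naive and quiescence genes fell for 7 of 18 members (13 adjusted over the list alone, fry adjusted p = 0.0813). Memory-like genes fell for 3 of 15 (4 adjusted over the list alone, fry adjusted p = 0.286), with Bcl2 at -1.66 ± 0.26 (adjusted p = 0.0153). They include Xcl1 at -1.95 ± 0.39 (adjusted p = 0.0342) and Sidt1 at -0.81 ± 0.17 (adjusted p = 0.0375). Cytotoxic effector genes went both ways, with Fasl among 3 that rose and Gzmm (-1.46 ± 0.23, adjusted p = 0.0157) the 1 that fell, of 16 (3 higher and 2 lower adjusted over the list alone, fry adjusted p = 0.352). Of 21 NK receptor genes Klra6 (-2.64 ± 0.39) and Klra5 (-2.50 ± 0.54, adjusted p = 0.0425) fell (4 adjusted over the list alone, fry adjusted p = 0.337). Immediate early genes rose for 3 of 19 (5 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.382), with Egr1 at 1.77 ± 0.22 (adjusted p = 0.00577). Inhibitory receptor and exhaustion genes rose for 3 of 17 and tissue residency genes for 3 of 15, with 1 lower (fry adjusted p = 0.188 and 0.0813). Of 18 effector differentiation genes edgeR called 0, with 6 at an unadjusted p under 0.05 and 2 called by DESeq2. Within naive-like clusters alone Gzmm (3.36), Klra6 (2.23), Xcl1 (0.84), Sidt1 (0.58) and Bcl2 (0.39) had the opposite sign, none past the threshold (adjusted p of 0.371 to 0.575, standard errors of 1.91 and 1.92 for Gzmm and Klra6). By fry 1 of 33 lists passed (8 at an unadjusted p under 0.05) and by camera 0 (2 at an unadjusted p under 0.05). Leaving out single libraries gave 0 to 2 lists. Lung epithelium genes rose for 3 of 11 (8 adjusted over the list alone, fry adjusted p = 0.0813), with Scgb1a1 at 5153.5 and 102 CPM in the 2 tumor libraries against 2.51 and 0.0594 in spleen. Of 8 stroma genes 1 rose (6 adjusted over the list alone, fry adjusted p = 0.163). Decreases were called for 2 of 13 macrophage or monocyte markers (4 adjusted over the list alone, fry adjusted p = 0.171), 1 of 12 B cell markers (fry adjusted p = 0.320) and 1 of 10 erythroid or platelet markers (fry adjusted p = 0.325). Of the 197 higher genes 49 had a larger share of the UMIs outside the CD8 T-like clusters in both sets, among them Nr4a3, Egr1 and Scgb1a1, and 90 in at least 1. Klra5 passed in none of the fits that left out 1 library.

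The tumor-spleen comparisons share no library. Across genes their log2 changes correlated with r of 0.654 (genes are not independent replicates). In both, 107 genes were higher in tumor (4.93 expected for independent lists) and 32 lower (2.08), and 0 had opposite calls. These lists are not independent: the same fit gave both, and both tumors hold lung RNA such as Scgb1a1. The difference between these tumor-spleen changes (null Ia+ minus C57BL/6) was tested as an interaction, and edgeR called 6 genes, all negative. Nsg2 changed by -2.67 ± 0.28 (adjusted p = 0.0224, -2.62 and -2.43 within the sets), Rflnb by -1.95 ± 0.24 (adjusted p = 0.0478, -1.70 and -1.98), Slpi by -3.35 ± 0.42 (adjusted p = 0.0479, -3.34 and -2.26) and the B cell gene Cd22 by -4.39 ± 0.50 (adjusted p = 0.0345, -2.21 and -3.38). The melanoma genes Dct and Tyrp1 were called too, resting on 83.0 and 76.3 CPM in the earlier C57BL/6 tumor library. Dapl1 (-3.49 ± 0.64, adjusted p = 0.28), Ccr7 (-2.62 ± 0.50, adjusted p = 0.28) and Bcl2 (-2.38 ± 0.37, adjusted p = 0.135) did not pass. Of 18 naive and quiescence genes edgeR called 0 in the interaction, with 9 lower at an unadjusted p under 0.05, 9 lower adjusted over the list alone and 5 lower by DESeq2 (fry adjusted p = 0.135, camera adjusted p = 0.152). Of 21 NK receptor genes it called 0, with 14 lower at an unadjusted p under 0.05, 7 lower adjusted over the list alone and 2 lower by DESeq2 (fry adjusted p = 0.135). By fry 0 of 33 lists passed, with 11 at an unadjusted p under 0.05, and by camera 0, with 9.

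The interaction count rested on single libraries. It was 0 without C57BL/6 spleen replicate 1 (418 at an unadjusted p under 0.05), without C57BL/6 tumor replicate 1 (511) and without null Ia+ spleen replicate 1 (464). It was 12 without C57BL/6 spleen replicate 2, 5 without C57BL/6 tumor replicate 2, 1 without null Ia+ spleen replicate 2, 7 without null Ia+ tumor replicate 1 and 13 without null Ia+ tumor replicate 2. None of the 6 genes passed in all 8 fits: Dct passed in 3, Nsg2, Slpi and Tyrp1 in 2, and Rflnb and Cd22 in 1. Rflnb had the opposite sign in all filtered cells (0.57) and in naive-like clusters (0.29). In a fit with no deposit-set term edgeR called 0 (249 at an unadjusted p under 0.05). DESeq2, with that term, called 69 (9 higher and 60 lower), and removing clusters led by another type's marker gave 10.

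Spleens of null mice given Ia+ or Ia- cells were compared to ask what injected cells bearing MHC class Ia change in CD8 T cells that lack it. Lgals1, a lectin gene of effector T cells (ENSMUSG00000068220, chromosome 15, 78926725 to 78930465), averaged 2906 ± 578 CPM (SD, n = 2) with Ia+ and 483 ± 36.3 with Ia- cells, and rose by 2.58 ± 0.24 (adjusted p = 0.0159, 2.70 and 2.45 within the sets). The DNA-binding protein gene Hmgb2 averaged 1135 CPM against 355 and rose by 1.68 ± 0.24 (adjusted p = 0.0396, 1.56 and 1.8). Also higher with Ia+ cells were AA467197 (6.02 ± 0.59, adjusted p = 0.0159, 4.90 and 3.73), Anxa1 (3.10 ± 0.45, adjusted p = 0.0449, 2.44 and 2.50), E2f2 (2.17 ± 0.26, adjusted p = 0.0226), Vim (1.66 ± 0.25, adjusted p = 0.0465) and Lmnb1 (1.64 ± 0.24, adjusted p = 0.0396). Gzma (chromosome 13, 113093825 to 113100981) averaged 4659 CPM against 75, with a fitted change of 6.13 ± 0.87 and adjusted p = 0.0678 (5.72 and 6.66). Gzmb averaged 528 ± 81.4 CPM against 32.3 ± 16.7. Within antigen-experienced-like clusters alone Hmgb2 (-0.27) and Lmnb1 (-0.37) had the opposite sign, as did Anxa1 (-0.13) and Lmnb1 (-0.11) within naive-like clusters. EdgeR called 25 genes, 25 higher and 0 lower (1112 at an unadjusted p under 0.05), while DESeq2 called 285 higher and 18 lower. Of the 25 genes 7 had a larger share of the UMIs outside the CD8 T-like clusters in both sets, among them Lmnb1 and Anxa1, and 18 in at least 1. Of 18 effector differentiation genes 2 rose (14 adjusted over the list alone, fry adjusted p = 0.162, camera adjusted p = 0.343 with an estimated correlation), and of 20 proliferation genes 1 rose (18 adjusted over the list alone, fry adjusted p = 0.162). Of 16 cytotoxic effector genes edgeR called 0, with 4 higher at an unadjusted p under 0.05, 3 higher adjusted over the list alone and 3 by DESeq2 (fry adjusted p = 0.522). Of 18 naive and quiescence genes it called 0, with 4 lower at an unadjusted p under 0.05 and 0 by DESeq2 (fry adjusted p = 0.827). Of 21 NK receptor genes it called 0, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 (fry adjusted p = 0.908). By fry 0 of 33 lists passed (4 at an unadjusted p under 0.05) and by camera 0 (3 at an unadjusted p under 0.05). The count of genes was 2 without null Ia+ spleen replicate 1, 1 without its replicate 2, 108 without null Ia- spleen replicate 1 and 0 without its replicate 2 (1293 at an unadjusted p under 0.05). None of 9 called genes named by the rule passed in all 4 fits, and 3 passed in none, Hmgb2 and Vim among them. Leaving out the deposit-set term gave 0 calls by edgeR (424 at an unadjusted p under 0.05). Leaving out the clusters led by another type's marker, which held 43.5% and 35.6% of the null Ia- cells, gave 67.

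Spleens of null Ia+ mice were set against C57BL/6 spleens, a comparison in which genotype and injected cells differ together. Some cytotoxic genes were higher in null Ia+ cells. Gzmb averaged 528 ± 81.4 CPM (SD, n = 2) against 16.7 ± 12.2 and rose by 5.04 ± 0.64 (adjusted p = 0.00867, 6.02 and 4.16 within the sets). Gzma rose by 5.04 ± 0.83 (adjusted p = 0.0214, 6.67 and 4.25). The activating receptor gene Klrk1 (ENSMUSG00000030149, chromosome 6, 129610323 to 129623864) averaged 258 ± 147 CPM against 26.4 ± 14.3 and rose by 3.28 ± 0.36 (adjusted p = 0.00467, 3.27 and 3.16). The inhibitory receptor gene Klrc1 (chromosome 6, 129666015 to 129678973) rose by 3.83 ± 0.41 (adjusted p = 0.00425, 4.27 and 3.28). Lgals1 averaged 2906 CPM against 426 and rose by 2.74 ± 0.25 (adjusted p = 0.00309, 3.21 and 2.34). Fasl rose by 3.43 ± 0.38 (adjusted p = 0.00431, 3.42 and 2.83). The chemokine genes Ccl5 (22786 CPM against 2140, 3.39 ± 0.65, adjusted p = 0.0284) and Ccl3 (4.78 ± 0.74, adjusted p = 0.0157) rose. Als2cl (-2.34 ± 0.24, adjusted p = 0.00361, -2.29 and -2.21), the homing receptor gene Ccr7 (-1.74 ± 0.36, adjusted p = 0.0278, -1.52 and -1.97) and Actn1 (-1.70 ± 0.33, adjusted p = 0.0235) fell. H2-D1 fell with a log2 change of -10.99 ± 0.28 (adjusted p = 3e-07) and H2-K1 with -3.09 ± 0.33 (adjusted p = 0.00408), while B2m did not pass (0.08 ± 0.16, adjusted p = 0.832). EdgeR called 683 genes, 540 higher and 143 lower in null Ia+ spleen, 678 of them with the same sign in both sets. The count was 65 without C57BL/6 spleen replicate 1, 263 without its replicate 2, 67 without null Ia+ spleen replicate 1 and 83 without its replicate 2. Of 59 called genes named by the rule 18 passed in all 4 fits, among them Klrk1, Klrc1, Klra3, Lgals1, Fasl, H2-K1 and H2-D1. Another 29 passed in none, among them Ccl5, Ccl3, Ccl4, Itga1, Ccr7 and Actn1. Gzmb did not pass without null Ia+ spleen replicate 1 (adjusted p = 0.0572), and Gzma did not without either null Ia+ spleen library (adjusted p up to 0.128). A fit lacking the deposit-set term called 2 genes, and leaving out the clusters led by another type's marker gave 1100.

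In this spleen comparison 9 of 33 lists passed by fry (15 at an unadjusted p under 0.05) and 0 by camera with an estimated correlation (4 at an unadjusted p under 0.05). Leaving out any single library of the comparison gave 0 lists, and the fit without the deposit-set term gave 8. Effector differentiation genes rose for 15 of 18 members (17 adjusted over the list alone, fry adjusted p = 0.0247, camera adjusted p = 0.247), with Ccr2 at 3.05 ± 0.30 (adjusted p = 0.00311), Anxa2 at 2.46 ± 0.26 (adjusted p = 0.00394) and Itgb1 at 2.49 ± 0.29 (adjusted p = 0.00522). NK receptor genes rose for 11 of 21 (17 adjusted over the list alone, fry adjusted p = 0.0247), with Klra3 at 2.76 ± 0.30 (adjusted p = 0.00394). Cytotoxic effector genes rose for 8 of 16 (13 adjusted over the list alone, fry adjusted p = 0.0247), with Slamf7 at 2.85 ± 0.34 (adjusted p = 0.00522). Proliferation genes rose for 11 of 20 (18 adjusted over the list alone, fry adjusted p = 0.0420), with Hmgb2 at 1.97 ± 0.24 (adjusted p = 0.00522) and Stmn1 at 2.18 ± 0.38 (adjusted p = 0.0169). Naive and quiescence genes fell for 5 of 18 (13 adjusted over the list alone, fry adjusted p = 0.0420). Chemokine receptor and integrin genes rose for 6 and fell for 2 of 18 (8 and 3 adjusted over the list alone, fry adjusted p = 0.0420), with Ccr9 at -3.13 ± 0.43 (adjusted p = 0.00868). Tissue residency genes rose for 3 of 15 (6 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.0420), with Rgs1 at 3.08 ± 0.36 (adjusted p = 0.00522). The list of MHC Ia antigen presentation fell for 2 of 12 members, H2-K1 and H2-D1 (fry adjusted p = 0.0420), and its other 10 members did not pass. NK cell markers rose for 4 of 12 (11 adjusted over the list alone, fry adjusted p = 0.0420), a list that shares genes with effector CD8 T cells. Within naive-like clusters alone Lgals1 stood at -0.0275, and within antigen-experienced-like clusters Hmgb2 (-0.13), Stmn1 (-0.43) and Cd22 (-1.49) had the opposite sign. B cell markers rose for 2 of 12 (4 adjusted over the list alone, fry adjusted p = 0.115), Cd22 among them (3.71 ± 0.34, adjusted p = 0.0031). Of the 540 higher genes 154 had a larger share of the UMIs outside the CD8 T-like clusters in both sets and 345 in at least 1.

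Tumors of null Ia+ and C57BL/6 mice were compared to ask how tumor CD8 T cells differ when they lack H2-Kb and H2-Db. Genotype and injected cells again differed together, and so did melanoma RNA. Outside the CD8 T-like clusters the melanoma gene Dct stood at 5174 and 551 CPM in C57BL/6 tumor, earlier set first. In null Ia+ tumor it stood at 0.508 and 0 CPM there (no TMM factors). Naive-state genes were lower in null Ia+ tumor. Naive-like clusters held 5.03% and 1.00% of its CD8 T-like cells against 75.6% and 59.4% in C57BL/6 tumor. Cell mix was not told apart from change within cells. Ccr7 averaged 37.3 ± 14.3 CPM (SD, n = 2) against 782 ± 17.6 and changed by -4.37 ± 0.40 (adjusted p = 0.0015, -4.78 and -4.04 within the sets). Dapl1 (-5.59 ± 0.54, adjusted p = 0.00231, -5.44 and -5.29), Igfbp4 (-4.27 ± 0.37, adjusted p = 0.00122, -3.52 and -4.52) and the survival gene Bcl2 (-2.17 ± 0.27, adjusted p = 0.00412, -2.64 and -1.65) fell. Lgals1 averaged 4549.8 ± 1130 CPM against 1626 and rose by 1.48 ± 0.24 (adjusted p = 0.0106, 1.54 and 1.41). The NK receptor genes Klra3 (2.47 ± 0.30, adjusted p = 0.0037, 2.76 and 1.71) and Klrc1 (2.07 ± 0.38, adjusted p = 0.0188, 2.34 and 1.68), the transcription factor gene Tbx21 (1.64 ± 0.28, adjusted p = 0.0138, 1.90 and 1.33) and the glucose transporter gene Slc2a3 (1.63 ± 0.23, adjusted p = 0.00699) rose. Nkg7 (0.95 ± 0.20, adjusted p = 0.0315) and Fasl (1.45 ± 0.34, adjusted p = 0.0431) rose and passed in none of the fits that left out 1 library. Gzma (2.50 ± 0.73, adjusted p = 0.108) and Mki67 (1.58 ± 0.50, adjusted p = 0.12) did not pass. H2-D1 changed by -11.43 ± 0.28 (adjusted p = 2.22e-07) and H2-K1 by -2.51 ± 0.32 (adjusted p = 0.00538). H2-K1 did not pass when null Ia+ tumor replicate 1 was left out (adjusted p = 0.057), and B2m did not pass in the fit of all libraries (0.04 ± 0.16, adjusted p = 0.92). EdgeR called 693 genes, 205 higher and 488 lower in null Ia+ tumor, 691 of them with the same sign in both sets. DESeq2 called 608 higher and 727 lower, and edgeR called 28 and 26 within antigen-experienced-like and 7 and 5 within naive-like clusters. The count was 198 without C57BL/6 tumor replicate 1, 127 without its replicate 2, 386 without null Ia+ tumor replicate 1 and 1216 without its replicate 2. In all 4 fits 8 of 44 called genes named by the rule passed (Ccr7, Dapl1, Igfbp4, Bcl2, Klra3, AA467197, Tmem108 and H2-D1). Dropping the deposit-set term gave 13 genes, and dropping the clusters led by another type's marker gave 887.

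Naive and quiescence genes fell for 15 of 18 members between the tumors (17 adjusted over the list alone, fry adjusted p = 0.0237, camera adjusted p = 0.559 with an estimated correlation), the 1 list of 33 past the fry threshold (8 at an unadjusted p under 0.05, 0 to 1 lists with single libraries left out). Camera passed 0 (2 at an unadjusted p under 0.05). Effector differentiation genes rose for 7 of 18 (17 adjusted over the list alone, fry adjusted p = 0.0863), with Itgb1 at 1.59 ± 0.28 (adjusted p = 0.0159). Cytotoxic effector genes rose for 3 of 16 (8 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.134), with Slamf7 at 1.40 ± 0.32 (adjusted p = 0.0401). Memory-like genes fell for 3 of 15 (2 higher and 4 lower adjusted over the list alone, fry adjusted p = 0.291), with Slamf6 at -2.35 ± 0.52 (adjusted p = 0.0401, -3.50 and -1.56). Chemokine receptor and integrin genes rose for 2 and fell for 4 of 18 (10 and 4 adjusted over the list alone, fry adjusted p = 0.447), with Itga1 at 3.22 ± 0.61 (adjusted p = 0.024) and Ccr9 at -3.78 ± 0.46 (adjusted p = 0.00428). Apoptosis and survival genes rose for 4 and fell for 2 of 16 (5 and 5 adjusted over the list alone, fry adjusted p = 0.836). NK receptor genes rose for 2 and fell for 1 of 21 (fry adjusted p = 0.447). Inhibitory receptor genes rose for 1, Cd244a (1.76 ± 0.43, adjusted p = 0.0491), and fell for 1, Ikzf2 (-1.73 ± 0.32, adjusted p = 0.0174, in none of the fits that left out 1 library), of 17 (fry adjusted p = 0.291). Within naive-like clusters alone Igfbp4 (0.34) and Ikzf2 (0.0296) had the opposite sign. Of 20 proliferation genes edgeR called 0, with 7 higher at an unadjusted p under 0.05 and 4 by DESeq2 (fry adjusted p = 0.291). Melanoma markers fell for 2 of 5 (5 adjusted over the list alone, fry adjusted p = 0.134), Dct at 0.091 CPM and Tyrp1 at 0.182 CPM on average in null Ia+ tumor. Of the 205 higher genes 29 had a larger share of the UMIs outside the CD8 T-like clusters in both sets, Cd244a among them, and 93 in at least 1.

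**Figure D3:**
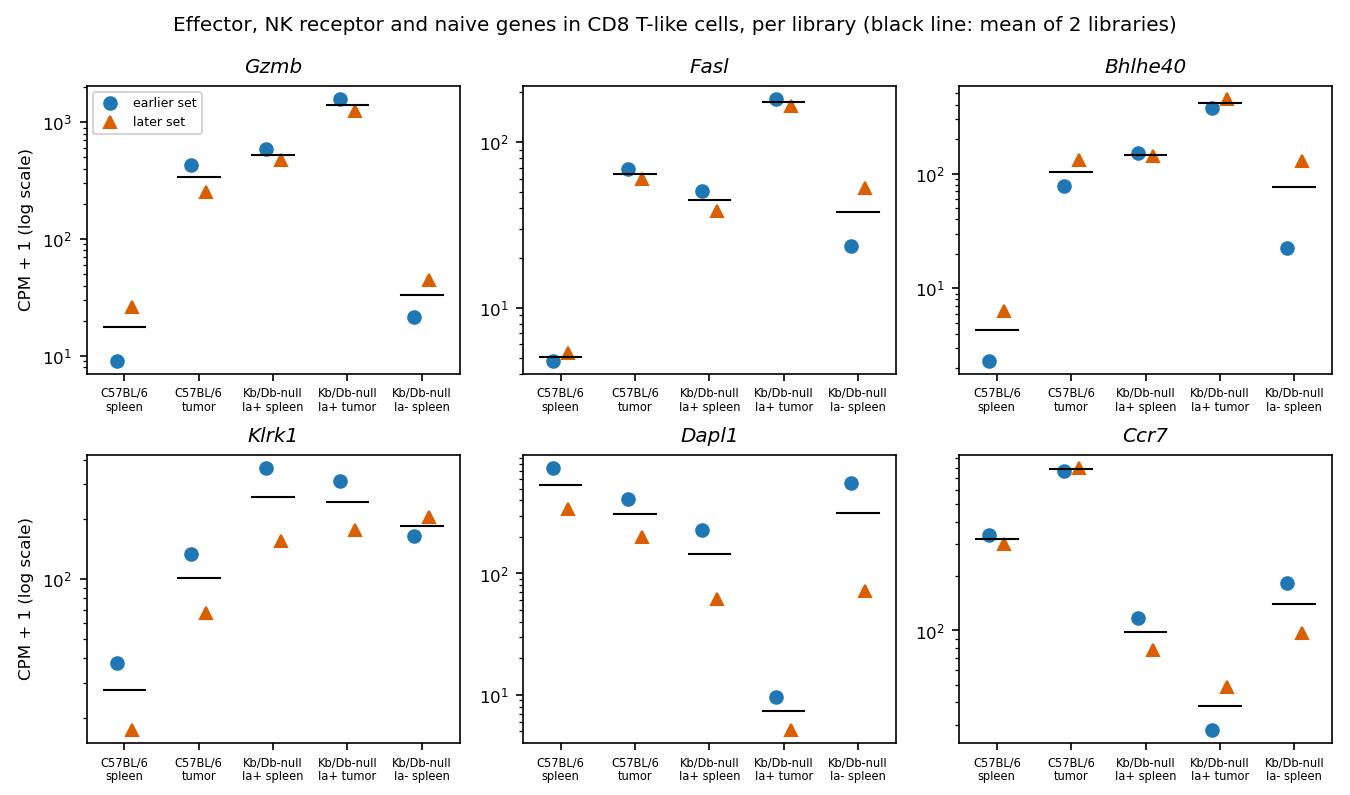
CPM plus 1 (log scale) of Gzmb, Fasl, Bhlhe40, Klrk1, Dapl1 and Ccr7 in CD8 T-like cells of each library, with a black line at the mean of the 2 libraries of each group. Gzmb averages 1409 CPM in null Ia+ tumor and 16.7 CPM in C57BL/6 spleen, and Dapl1 averages 6.33 CPM in null Ia+ tumor and 539 CPM in C57BL/6 spleen.

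Spleens of null Ia- mice against C57BL/6 spleens compared the null genotype, with injected cells that lack class Ia, with the wild type. Some NK receptor genes were higher in null Ia- cells. Klrk1 averaged 184 ± 27.8 CPM (SD, n = 2) against 26.4 ± 14.3 and rose by 3.00 ± 0.36 (adjusted p = 0.0183, 2.14 and 3.56 within the sets). Klrc1 rose by 2.99 ± 0.40 (adjusted p = 0.023, 2.67 and 3.08), Klra6 by 2.41 ± 0.39 (adjusted p = 0.0435, 2.13 and 2.27) and Klra3 by 2.31 ± 0.30 (adjusted p = 0.0187, 2.49 and 1.66). Fasl (3.18 ± 0.37, adjusted p = 0.0183, 2.30 and 3.30), Rgs1 (2.96 ± 0.36, adjusted p = 0.0183, 3.03 and 2.80), the granzyme gene Gzmm (1.88 ± 0.24, adjusted p = 0.0183, 1.59 and 2.10) and Ccr2 (1.78 ± 0.29, adjusted p = 0.0405) rose too. Als2cl (-1.86 ± 0.23, adjusted p = 0.0183, -1.62 and -2.0), Actn2 (-2.19 ± 0.31, adjusted p = 0.0258) and Trib2 (-1.43 ± 0.24, adjusted p = 0.0435) fell. Within antigen-experienced-like clusters alone Ccr2 (-0.74, adjusted p = 0.675) and Gzmm (-0.13, adjusted p = 1) had the opposite sign. H2-D1 changed by -11.36 ± 0.29 (adjusted p = 2.81e-07) and H2-K1 by -3.38 ± 0.34 (adjusted p = 0.00742), and B2m did not pass (0.03 ± 0.16, adjusted p = 0.984). EdgeR called 65 genes, 52 higher and 13 lower in null Ia- spleen, 65 of them with the same sign in both sets. Of the 52 higher genes 10 had a larger share of the UMIs outside the CD8 T-like clusters in both sets, Rgs1 among them, and 28 in at least 1. NK receptor genes rose for 4 of 21 members (16 adjusted over the list alone, fry adjusted p = 0.0692, camera adjusted p = 0.244 with an estimated correlation) and cytotoxic effector genes for 2 of 16 (8 adjusted over the list alone, fry adjusted p = 0.0700). Effector differentiation genes rose for 2 of 18 (9 adjusted over the list alone, fry adjusted p = 0.127), and inhibitory receptor genes for 1 of 17, Tigit (3.76 ± 0.62, adjusted p = 0.0495, 0.60 and 3.82; 9 adjusted over the list alone, fry adjusted p = 0.0997). Of 15 memory-like genes edgeR called 0, with 8 higher and 1 lower adjusted over the list alone, 10 at an unadjusted p under 0.05 and 6 by DESeq2. Of 20 proliferation genes it called 0, with 1 lower at an unadjusted p under 0.05 and 1 by DESeq2 (fry adjusted p = 0.922). Among markers of other cells 1 of 12 B cell genes rose, Cd22 (5 adjusted over the list alone, fry adjusted p = 0.154). Of 12 NK cell markers edgeR called 0, with 9 higher at an unadjusted p under 0.05, 7 adjusted over the list alone and 6 by DESeq2 (fry adjusted p = 0.143). Of 13 macrophage or monocyte markers it called 0, with 3 higher at an unadjusted p under 0.05 and 0 by DESeq2 (fry adjusted p = 0.204). By fry 0 of 33 lists passed (10 at an unadjusted p under 0.05), and by camera 0 (5 at an unadjusted p under 0.05). With single libraries left out 0 to 2 lists passed by fry, and 12 without the clusters led by another type's marker. The count of genes was 9 without C57BL/6 spleen replicate 1, 18 without its replicate 2, 319 without null Ia- spleen replicate 1 and 11 without its replicate 2. Of 19 called genes named by the rule Cd22, H2-K1 and H2-D1 passed in all 4 fits. Klrk1 did not pass without either C57BL/6 spleen library (adjusted p up to 0.135). With the deposit-set term left out the count was 2, and with the clusters led by another type's marker left out it was 326.

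Shares of CD8 T-like cells with a UMI, after thinning each cell to 1000 UMIs, gave Gzmb in 0.558% (0.399% to 0.759%) and 1.24% (0.996% to 1.52%) of cells in C57BL/6 spleen and in 13.5% (12.0% to 15.1%) and 11.9% (11.1% to 12.7%) in C57BL/6 tumor. Gzmb was detected in 27.5% (26.0% to 28.9%) and 23.6% (22.4% to 24.8%) of cells in null Ia+ spleen, 69.0% (67.7% to 70.2%) and 48.8% (47.5% to 50.1%) in null Ia+ tumor, and 1.19% (0.873% to 1.60%) and 5.21% (4.70% to 5.75%) in null Ia- spleen. Without thinning these Gzmb shares were 1.19% and 2.75%, 21.6% and 21.2%, 43.9% and 40.8%, 91.8% and 74.1%, and 2.63% and 12.9%. B-like cells of the same libraries held Gzmb in 0 cells apart from 1 of 17 (5.88%) in the earlier C57BL/6 tumor library and 1 of 657 (0.152%) in the later null Ia- spleen library. Klrk1 was detected in 24.9% and 14.7% of null Ia+ spleen cells and in 10.2% and 21.2% of null Ia- spleen cells, against 2.19% and 1.43% in C57BL/6 spleen. Its unthinned shares were 46.4% and 41.9%, 17.3% and 46.5%, and 4.31% and 3.67%, and B-like cells held it in up to 4.82% (of 83 cells). Median depths of CD8 T-like and B-like cells were 2640.5 and 2526 UMIs in the earlier null Ia- spleen library and 7034 and 3831 in the later null Ia+ tumor library, the lowest and the highest of CD8 T-like cells. No earlier cell and 13 to 37 cells of each later library lay under 1000 UMIs and were left out.

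T cell receptor beta variable genes could be counted in the later set alone, with 1 library per group and no test. UMIs of 1 cell are not independent, so no intervals are given. Null Ia+ tumor held 72478 Trbv UMIs, of which Trbv16 took 30.9%. Its share was 14.9% in null Ia+ spleen, 8.88% in C57BL/6 spleen, 8.32% in C57BL/6 tumor and 3.69% in null Ia- spleen. Trbv12-2 took 24.1% of 27231 Trbv UMIs in null Ia- spleen. It took 7.30%, 7.35%, 4.59% and 2.79% in C57BL/6 spleen, C57BL/6 tumor, null Ia+ spleen and null Ia+ tumor. The effective number of Trbv genes was 17.4 in C57BL/6 spleen, 16.5 in C57BL/6 tumor, 15.3 in null Ia+ spleen, 10.5 in null Ia+ tumor and 13.2 in null Ia- spleen.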

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

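Both tests of the spleen pattern below (the mix of cell states and RNA of other cells) were chosen only after the result was seen. The tests of the tumor and NK receptor patterns were set before their results were seen.

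The tumor-spleen difference differed between null Ia+ and C57BL/6 mice for 6 genes, by a test of the interaction itself. Nsg2 differed by -2.67 on the log2 scale, Rflnb by -1.95, Slpi by -3.35 and the B cell gene Cd22 by -4.39. Dct differed by -11.19 and Tyrp1 by -12.62. These fitted values depend on the prior count and are no bounds, because both genes rest on the earlier C57BL/6 tumor library, with 83.0 and 76.3 CPM there. In null Ia+ spleen Slpi stood at 932 and 925 CPM outside the CD8 T-like clusters against 43.6 and 15.2 inside, and Cd22 at 1.06 and 104 against 4.12 and 16.8 (earlier set first, no TMM factors). No technical explanation was tested for Nsg2, Rflnb, Slpi or Cd22. RNA of other cells, the genotype, the injected cells and chance stay open for them. Of the 8 fits that left out 1 library, Nsg2 and Slpi passed in 2, and Rflnb and Cd22 in 1.

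Cells of other types stood above 5% of the filtered cells in a bead-isolated CD8 fraction, outside the comparisons of CD8 T-like cells. The earlier C57BL/6 tumor library held 29.0% melanoma-like and 8.51% epithelial-like cells. The earlier null Ia+ tumor library held 9.06% NK-like and 7.46% stromal-like cells. In the earlier null Ia+ spleen library erythroid- or platelet-like cells were 9.64%, NK-like cells 6.73% and mast- or basophil-like cells 5.0%. The later null Ia+ spleen library held 5.45% B-like and 5.37% macrophage-like cells, and the later null Ia- spleen library 7.53% B-like cells. The limit of 5% was set after the data were seen, and no explanation of these shares was tested.

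Lung genes were higher in tumor than in spleen sums of CD8 T-like cells in both kinds of mice. Melanoma genes were higher in C57BL/6 mice alone, and in null Ia+ mice 0 of them had an unadjusted p under 0.05. Expression by the tumor CD8 T cells themselves was argued against, since the level per cell in CD8 T-like over that in NK-like cells had a median ratio of 1.09 over 23 genes in the earlier C57BL/6 tumor library and 1.05 over 19 genes in the earlier null Ia+ tumor library, where a ratio over 2 was needed. Free RNA from lung and tumor cells is a candidate explanation. In both earlier tumor libraries 100% of CD8 T-like cells held a UMI of Scgb1a1, at a median of 12 and 18 UMIs, beside 13 and 18 in NK-like cells. Doublets or misplaced cells stay open, because the 5% of CD8 T-like cells with most Scgb1a1 held 42.5% of its UMIs in the C57BL/6 and 19.2% in the null Ia+ library. Under 25% in both was needed to argue against them, and over 50% in both to support them.

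Genes were changed between null Ia+ and C57BL/6 spleen. RNA of other cells as the source of most increases stays open. Of the 540 genes that rose, 47.6% (exact binomial 95% interval 43.3% to 51.9%) and 44.8% (40.6% to 49.1%) had a larger share of the UMIs outside the CD8 T-like clusters in the earlier and later null Ia+ spleen library. The first interval includes the bound of 50%, which has no baseline over all tested genes, and genes are not independent. A different mix of naive-like and antigen-experienced-like cells might explain the change, and this cannot be told apart from a change within cells. Of the 540 genes, 330 were tested in naive-like and 524 in antigen-experienced-like cells. They kept fractions of 0.389 (0.66 of 1.70) and 0.305 (0.67 of 2.20) of their median log2 change (2.24 over all 540). Both lie between the bounds of 0.25 and 0.5. Clusters with neither state, outside this test, held 29.8% and 52.0% of the CD8 T-like cells of null Ia+ spleen and 14.6% and 15.1% of C57BL/6 spleen. Clusters were built on these genes, which keeps the question open, as are genotype and injected cells.

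The NK receptor genes Klrk1, Klrc1, Klra3 and Klra6 stood higher in both kinds of null spleen than in C57BL/6 spleen. NK cells or their RNA among the CD8 T-like cells were argued against only in part. Tyrobp is 1 of the NK markers that barred clusters from the CD8 T-like name, so the naming itself limits its level there. Tyrobp, abundant in NK cells, gained at most 0.0983 of what the receptor genes would bring with them, over 4 null spleen libraries, the others being 0.0450, 0.00939 and 0.00437, where under 0.5 was set as evidence against. In the later set the NK profile came from 6 and 8 cells. A change in the CD8 T cells themselves is a hypothesis for the receptor genes, found and tested on the same data. Genotype and injected cells differ together from C57BL/6 mice, and a difference in cell states stays open.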

How the results depend on the processing

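Removal of the highest 6% of doublet scores and of the clusters led by another type's marker were chosen only after the data were seen, and all other alternatives before. Comparisons are listed in 1 order: C57BL/6 tumor against spleen, null Ia+ tumor against spleen, Ia+ against Ia- spleen, null Ia+ against C57BL/6 spleen, null Ia+ against C57BL/6 tumor, null Ia- against C57BL/6 spleen, and the interaction. The counts of changed genes were 424, 466, 25, 683, 693, 65 and 6.

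All 7 counts stayed within 1.5 times of these values with 5% mitochondrial UMIs, with called doublets kept and with the highest 6% of doublet scores removed. RLE size factors did so for 6 of 7, with 3 genes in the interaction. DESeq2 called more in each comparison: 1176, 1196, 303, 1275, 1335, 448 and 69. Without a low-count filter 4 of 7 stayed, with counts of 479, 521, 78, 678, 719, 145 and 11. Libraries thinned to the smallest total gave 43 for Ia+ against Ia- spleen and 0 for the interaction (706 at an unadjusted p under 0.05), and 5 of 7 stayed. Without the replicate block (the deposit-set term) edgeR called 0, 0, 0, 2, 13, 2 and 0 genes (1074, 1001, 424 and 249 at an unadjusted p under 0.05 where it called 0). The cause was not tested for any of these.

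The counts also moved with the cell population. All filtered cells gave 95, 6, 0, 0, 14 and 0 genes in the first 6 comparisons (107, 1617 and 818 at an unadjusted p under 0.05 where the count was 0). Cells gated by UMIs gave 52, 80, 0, 83, 63, 2 and 3 (393 at an unadjusted p under 0.05 for the 0). Antigen-experienced-like clusters alone gave 65, 224, 47, 55, 54, 18 and 0 (162 at an unadjusted p under 0.05 for the 0). Naive-like clusters alone gave 732, 409, 0, 34, 12, 30 and 0 (204 and 513 at an unadjusted p under 0.05 for the 0 counts). Removing clusters led by another type's marker gave 641, 528, 67, 1100, 887, 326 and 10. The cause was not tested, though each population holds other cells by construction.

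Leaving out 1 library gave 2 to 237 genes for C57BL/6 tumor, 24 to 996 for null Ia+ tumor against spleen, 0 to 108 for Ia+ against Ia- spleen, 65 to 263 for null Ia+ against C57BL/6 spleen, 127 to 1216 between tumors, 9 to 319 for null Ia- against C57BL/6 spleen and 0 to 13 for the interaction. Such a fit has 1 library in a group, which is assumed to vary like the other groups, and 1 residual degree of freedom fewer.

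Gene lists past the fry threshold numbered 0, 1, 0, 9, 1, 0 and 0. With 1 library left out they numbered 0 to 6, 0 to 2, 0 to 0, 0 to 0, 0 to 1, 0 to 2 and 0 to 3. Without the replicate block they were 3 in C57BL/6 tumor and 2 in null Ia+ tumor against spleen. Camera passed 0 lists in each comparison, with 5, 2, 3, 4, 2, 5 and 9 at an unadjusted p under 0.05. Antigen-experienced-like clusters gave 1, 4, 0, 5, 3, 0 and 0 lists. Removing clusters led by another type's marker gave 10, 2, 0, 12, 4, 12 and 4 lists. The cause was not tested.

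Of 260 named calls, 260 kept their direction with RLE, DESeq2, no low-count filter, no replicate block, 5% mitochondrial UMIs, doublets kept, the highest doublet scores removed and clusters led by another type's marker removed. Their calls were kept for 253, 247, 231, 5, 254, 260, 252 and 252 of them. In all cells 14 calls were kept and 6 reversed: Srgn (-0.0534) in C57BL/6 tumor, G0s2 (1.22) and Igfbp4 (0.19) in null Ia+ tumor against spleen, Pecam1 (0.50) and Sidt1 (0.21) between tumors, and Rflnb (0.57) in the interaction. In gated cells 82 of 259 calls were kept, and Sftpc reversed between null Ia+ and C57BL/6 spleen (-2.46). In antigen-experienced-like clusters 89 of 249 were kept and 12 reversed. These were Tyms (-0.30) in C57BL/6 tumor, Xcl1 (0.12) in null Ia+ tumor against spleen, and Lmnb1 (-0.37) and Hmgb2 (-0.27) for Ia+ against Ia- spleen. They were Sftpc (-1.20), Stmn1 (-0.43), Cd22 (-1.49), Gzmm (-0.57) and Hmgb2 (-0.13) for null Ia+ against C57BL/6 spleen, and Ccr2 (-0.74), Tdrp (0.37) and Gzmm (-0.13) for null Ia- against C57BL/6 spleen. In naive-like clusters 85 of 233 were kept and 17 reversed. For null Ia+ tumor against spleen these were Rflnb (0.46), Sidt1 (0.58), Xcl1 (0.84), Cxcl10 (-1.34), Cxcr5 (0.14), Gzmm (3.36), Bcl2 (0.39) and Klra6 (2.23). Lmnb1 (-0.11) and Anxa1 (-0.13) reversed for Ia+ against Ia- spleen, and Pecam1 (0.0436), Sftpc (-1.68) and Lgals1 (-0.0275) for null Ia+ against C57BL/6 spleen. Igfbp4 (0.34), Sidt1 (0.58) and Ikzf2 (0.0296) reversed between tumors, and Rflnb (0.29) in the interaction. With 1 library left out, Tyrp1 ranged from -2.58 to 7.63 and Sftpc from -2.20 to 6.06 between null Ia+ and C57BL/6 spleen, both reversed without C57BL/6 spleen replicate 1. The cause was not tested for these reversals.

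The percent of CD8 T-like cells left its interval with 5% mitochondrial UMIs in the earlier C57BL/6 tumor library (43.6%) and in the later C57BL/6 spleen (94.7%), null Ia+ spleen (80.4%), null Ia+ tumor (94.2%) and null Ia- spleen (82.6%) libraries. With Leiden resolution 0.5 it was 97.1% in C57BL/6 spleen, 57.6% in null Ia+ spleen and 66.4% in null Ia- spleen of the earlier set, and 77.7% in null Ia+ spleen of the later set. With resolution 2 it was 97.0% in C57BL/6 spleen and 65.0% in null Ia- spleen of the earlier set, and 91.7% in null Ia+ tumor of the later set. Percents of other cell types left their intervals for 9 of 150 values with 5% mitochondrial UMIs, 23 with resolution 0.5 and 41 with resolution 2. Melanoma-like cells of the earlier C57BL/6 tumor library were 24.2% with 5% mitochondrial UMIs, and erythroid- or platelet-like cells of the earlier null Ia+ spleen library 2.36% with resolution 2. The cause was not tested. Shares of cells with a UMI moved outside their interval for 87 of 110 values when cells were thinned to 1500 UMIs and for 110 of 110 with no thinning, which depth sets by construction.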

Other observations

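No test in this part was chosen after its result was seen, while the counts of alpha variable genes were added after the data were seen. Values of several gene groups belong beside the comparisons above. Oxidative phosphorylation genes (20 tested) passed in none of the 7 comparisons by edgeR. From C57BL/6 tumor against spleen on, in the order used for the processing alternatives, 1, 2, 1, 1, 0, 0 and 0 members had an unadjusted p under 0.05, and DESeq2 called 1 in null Ia+ tumor against spleen and 0 elsewhere. Interferon response genes (20 tested) were called in null Ia+ tumor against spleen alone, with Irf7 higher (1.61 ± 0.35, adjusted p = 0.0438), and 3, 2, 1, 1, 2, 0 and 0 members had an unadjusted p under 0.05 (0, 1, 0, 1, 1, 0 and 0 by DESeq2). The fry adjusted p of that list was 0.883 in C57BL/6 and 0.720 in null Ia+ tumor against spleen. Of 18 T cell receptor signalling genes 1 rose in C57BL/6 tumor (fry adjusted p = 0.507) and 2 in null Ia+ tumor (fry adjusted p = 0.337), with Icos at 1.68 ± 0.30 (adjusted p = 0.0235) in C57BL/6 and 1.89 ± 0.30 (adjusted p = 0.0153) in null Ia+ mice.

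Of 17 glycolysis genes 1 rose in C57BL/6 tumor, Slc16a3 (2.55 ± 0.51, adjusted p = 0.0364, list fry adjusted p = 0.0652), 1 in null Ia+ tumor against spleen (Hif1a, 1.23 ± 0.22, adjusted p = 0.022, list fry adjusted p = 0.163) and 4 in null Ia+ against C57BL/6 spleen, among them Pfkp (1.13 ± 0.19, adjusted p = 0.0137, list fry adjusted p = 0.0660). Of 12 heat shock and dissociation genes 2 rose in C57BL/6 tumor (fry adjusted p = 0.310), Hspa5 among them (1.32 ± 0.24, adjusted p = 0.0253), and 0 passed in null Ia+ tumor against spleen by edgeR, with 2 at an unadjusted p under 0.05 and 2 by DESeq2 (fry adjusted p = 0.720). Of 16 cytokine and chemokine genes 1 rose in C57BL/6 tumor, Cxcl10 (2.84 ± 0.43, adjusted p = 0.0162, list fry adjusted p = 0.174), and 4 rose in null Ia+ against C57BL/6 spleen (8 higher and 1 lower adjusted over the list alone, fry adjusted p = 0.0558). Of 15 memory-like genes Cd44 rose in C57BL/6 tumor (1.23 ± 0.27, adjusted p = 0.0488, list fry adjusted p = 0.326), and 3 rose in null Ia+ against C57BL/6 spleen (fry adjusted p = 0.155), Cd44 (1.60 ± 0.27, adjusted p = 0.0156) and Ly6c2 (1.23 ± 0.19, adjusted p = 0.0118) among them. In C57BL/6 tumor Slc16a3, Hspa5, Cxcl10 and Cd44 had a larger share of the UMIs outside the CD8 T-like clusters than inside in both sets, with Slc16a3 at 109 and 37.5 CPM outside against 5.64 and 2.20 inside (no TMM factors). The same held for Cd44 in null Ia+ spleen. With 1 library left out, Cd44 and Ly6c2 against C57BL/6 spleen and Icos in C57BL/6 tumor passed in 0 of 4 fits, and Pfkp in 1. Fatty acid and sterol genes rose for 1 and fell for 1 of 15 in C57BL/6 tumor (fry adjusted p = 0.0936).

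MHC Ib genes (13 tested) passed in neither tumor against spleen comparison by edgeR, with 1 and 4 members at an unadjusted p under 0.05 and 0 and 1 by DESeq2 (fry adjusted p = 0.80 and 0.320). H2-T3, at 1.79 CPM in null Ia- and 0.034 CPM in C57BL/6 spleen, was the 1 member that rose in null Ia- against C57BL/6 spleen (fry adjusted p = 0.541). The same count of 1 was seen for null Ia+ against C57BL/6 spleen (fry adjusted p = 0.424) and between tumors (fry adjusted p = 0.134). In MHC Ia antigen presentation 0 of 12 genes passed in C57BL/6 tumor (1 at an unadjusted p under 0.05, 0 by DESeq2, fry adjusted p = 0.827).

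Markers of other cell types were tested as lists in C57BL/6 tumor against spleen. By edgeR 1 of 8 CD4 T cell markers rose (fry adjusted p = 0.167), as did 1 of 13 macrophage or monocyte markers (fry adjusted p = 0.336) and 1 of 6 mast or basophil markers (fry adjusted p = 0.186). A decrease was called for 1 of 5 neutrophil markers (fry adjusted p = 0.883) and 1 of 10 erythroid or platelet markers (fry adjusted p = 0.838). None was called among 12 B cell markers (4 at an unadjusted p under 0.05, 2 by DESeq2, fry adjusted p = 0.219), 12 NK cell markers (10 and 8, fry adjusted p = 0.128), 4 gamma-delta or NKT markers (1 and 0, fry adjusted p = 0.161) and 6 dendritic markers (3 and 3, fry adjusted p = 0.326). The median, mean and test of a list differed in sign for MHC Ib, neutrophil and erythroid or platelet genes in this comparison. They did for cytokine and chemokine genes and chemokine receptor and integrin genes in null Ia+ tumor against spleen, for fatty acid and sterol genes in both comparisons of null Ia+ spleen and in the interaction, and for MHC Ib, neutrophil, mast or basophil and lung epithelium genes for Ia+ against Ia- spleen. The same held for heat shock, CD4 T cell and dendritic genes for null Ia+ against C57BL/6 spleen, for oxidative phosphorylation, apoptosis and survival, dendritic, neutrophil and erythroid or platelet genes between tumors, and for proliferation and dendritic genes for null Ia- against C57BL/6 spleen.

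T cell receptor alpha variable genes were counted in the later set, with 1 library per group, no test and no intervals. Trav16n took 20.3% of 25452 Trav UMIs in null Ia+ tumor. It took 8.07% in null Ia+ spleen, 3.36% in C57BL/6 spleen, 3.44% in C57BL/6 tumor and 2.19% in null Ia- spleen. Trav17 took 15.8% of 6567 Trav UMIs in null Ia- spleen and 0.691% to 5.78% in the other groups. The effective number of Trav genes was 53.8 in C57BL/6 spleen, 47.0 in C57BL/6 tumor, 36.3 in null Ia+ spleen, 18.2 in null Ia+ tumor and 28.4 in null Ia- spleen.

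After thinning to 1000 UMIs, Mki67 was detected in 4.21% and 8.34% of CD8 T-like cells of null Ia+ tumor, 2.70% and 6.11% of null Ia+ spleen, 0.864% and 2.20% of C57BL/6 tumor, 0.531% and 1.04% of null Ia- spleen, and 0.0697% and 0.774% of C57BL/6 spleen, earlier set first. Pdcd1 was detected in 0.571% and 11.7% of null Ia+ tumor cells.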
